A study of Homo sapiens with 12 samples.

How the data were processed

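Poly(A) RNA from HT-29 cells was made into strand-marked (dUTP) paired-end libraries of 150 bases per read, per the labels' protocols. The 12 samples fall into 4 groups of 3 by their treatment labels: control, 4-HDHA, TNF and TNF+4-HDHA. The dose of 4-HDHA is written in the design text with a unit of length and was read as 600 nM.

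The authors deposited a table of raw read counts per gene and a table of FPKM values per gene with coordinates and annotation terms, per the file headers. The FPKM values deposited by the authors are normalised for gene length and library size. Per the submitters' processing notes the tools were cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2. Which tool made which table, the genome build, and whether counting used strand are not given in the sources used here. Coordinates in the FPKM table overlapped the GRCh38 position in GENCODE release 29 for 99.9% of the 35241 genes found in both. Because the use of strand is unknown, overlapping and antisense genes are uncertain, as are genes that share reads with near-identical copies, including HLA genes, IFITM genes, histone genes and ribosomal protein genes with pseudogenes. There were 61806 genes in the count table and 37108 genes with FPKM, and the 24698 genes in the count table alone held 9 counts in all.

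Counts per library ranged from 54 M (TNF+4-HDHA replicate 1) to 62 M (control replicate 2), with 58 to 60.1 M in the 4-HDHA libraries. Floors for genes with a group at 0 take 3 counts over the group and cover counting error only, as the reads carry no molecular identifiers. No pair of replicates agreed within sampling noise: the lowest chi-square per degree of freedom was 9.68.

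All comparisons used edgeR 4.0.16 in R 4.3.3 on the deposited counts: filterByExpr by group with a minimum count of 10 and a total of 15, TMM scaling (factors 0.97 to 1.03), and a robust quasi-likelihood fit with 4 group means over all 12 libraries (8 residual degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were TNF against control, TNF+4-HDHA against TNF, 4-HDHA against control, TNF+4-HDHA against 4-HDHA, and the interaction. TNF-responsive genes for the signed interaction were chosen by the mean TNF effect of both backgrounds (adjusted p under 0.05 and a log2 fold change of at least 1 in size), a contrast orthogonal to the interaction. Standard errors come from the fit, and none is given for genes with a group at 0.

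Gene lists, 38 in all including 4 of markers of other cell types, were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01 and again with an estimated correlation, and with fry. Fry asks whether a list's genes move, on balance, in 1 direction, and compares them with no other genes. Fry called 28 lists for TNF, 1 for 4-HDHA under TNF, 3 for 4-HDHA without TNF, 31 for TNF in the presence of 4-HDHA and 7 for the interaction. The lists, designs, other settings and the rule for named genes were fixed before the data were examined.

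The rule named, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out rows with no symbol and symbols that begin with MSTRG, LOC or LINC or hold a dot. It added up to 4 called members of each list with the smallest p, or 2 members where none was called, and 16 fixed genes, among them PLIN2, ANGPTL4, CPT1A, PDK4, TNFAIP3, NFKBIA, BIRC3, CXCL8, CASP8, BCL2L1, MCL1, CFLAR, RIPK3 and MLKL. Single values of some genes chosen by the rule are not reported here. The text names part of these genes, a selection made after their values were seen, plus MEG3 and markers of skin and hair follicle.

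Other settings chosen in advance were RLE factors or library size in place of TMM, no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the libraries compared, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5 or no filter, and leaving out each library in turn. A fold on the log2(FPKM + pseudocount) scale understates the change of low genes, and only counts of calls were taken from it. The fit without control replicate 3, TNF replicate 1 and TNF+4-HDHA replicate 3, the library richest in hair-follicle transcripts of each of their groups, and an offset for GC content and transcript length (mgcv 1.9.3, values for 96.9% of tested genes) were chosen after seeing the data. Where a group keeps 2 libraries, or 1 against others, the spread is pooled over all groups.

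Other splits of the libraries were fitted for every comparison, 10 for each pair of groups and 60 drawn at random for the interaction, where the real split and the others alike were refitted with the dispersion estimated without the robust option and a robust quasi-likelihood fit. The tests of single genes, of lists and of the signed interaction were tried on simulated data. These were drawn from the real means and library sizes with 200 changed genes among 21104. The changed genes were taken from those with a mean of at least 5 CPM, and each gene had 1 spread for all groups. Recovery was thus not measured for lower genes or for the larger spread of the control. For log2 changes of 0.5, 1 and 2 in size, 71.6, 97 and 98.5% were recovered for TNF against control, 64.2, 94 and 98.5% for TNF+4-HDHA against TNF, 65.7, 92.5 and 100% for 4-HDHA against control, 66.7, 92.5 and 100% for TNF+4-HDHA against 4-HDHA, and 19.4, 74.6 and 98.5% for the interaction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.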

Results

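Gene expression was measured by RNA sequencing in HT-29 cells, a human colorectal carcinoma line, in 12 libraries that fall into 4 groups of 3. The groups were a control with 0.1% DMSO, 4-HDHA (a hydroxylated metabolite of docosahexaenoic acid), TNF (a cytokine that signals inflammation and can trigger cell death) and TNF with 4-HDHA. The labels write TNF at 100 ug/ml, a unit that could not be checked here, and 4-HDHA at a dose read as 600 nM because the written unit is a length. Treatment lasted 72 h. The stated aim was to learn how 4-HDHA acts on cells dying under TNF, with 4-HDHA alone as the check on undisturbed cells. The design text calls the replicates technical, so every p-value below measures only the spread between these libraries. Total counts per library ran from 54 to 62 M. Of 61806 genes counted, 21104 were tested. Levels are read counts scaled to library size (CPM) as mean ± SD over 3 libraries. Fold changes are log2 values ± SE with 3 libraries per group. Calls are adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

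Transcripts of hair follicle, which a culture of colon cells should not hold, were unevenly spread over the libraries. Hair-keratin and other hair-follicle markers summed to 88.7, 127 and 722 CPM in control replicates 1, 2 and 3, 912 in TNF replicate 1 and 121 in TNF+4-HDHA replicate 3. They summed to 3.65, 4.42 and 8.36 in the 4-HDHA libraries and 9.74 and 9.47 in the other TNF libraries and 8.96 and 11 in the other TNF+4-HDHA libraries. Fibroblast markers summed to 88.2 ± 61.6 CPM in the control (SD, n = 3), 19.4 ± 2.6 with 4-HDHA, 123 ± 7 with TNF and 91.1 ± 48.8 with TNF+4-HDHA. Control replicate 3 also stood apart from its group over all genes, with a chi-square per degree of freedom of 72.12 and 55.56 against control replicates 1 and 2, which gave 10.57 between themselves.

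**Figure D1:**
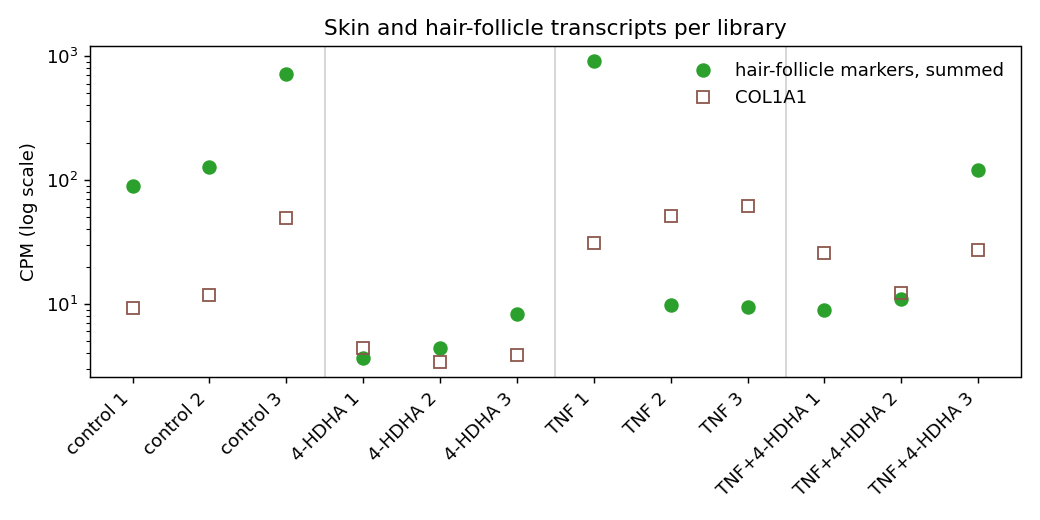
Summed CPM of hair-follicle markers (filled circles) and CPM of COL1A1 (open squares) in each of the 12 libraries, on a log axis. Hair-follicle markers reached 722 CPM in control replicate 3 and 912 CPM in TNF replicate 1, and stayed at or under 8.36 CPM in the 4-HDHA libraries.

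TNF against control asked what the cell-death stimulus changed. Of 6654 genes called, 3429 were higher and 3225 lower with TNF, and of these 894 and 484 changed at least 2-fold. The largest rises were in UBD, a ubiquitin-like modifier (8.30 ± 0.75, from 0.322 ± 0.558 to 95 ± 7.25 CPM), LTB, lymphotoxin beta (8.14 ± 0.54) and TNFRSF6B, a decoy receptor for Fas ligand (7.89 ± 0.77). They were followed by IL4I1, an amino-acid oxidase (7.02 ± 0.28), the acute-phase gene SAA1 (6.60 ± 0.30) and complement C3 (6.56 ± 0.62, from 5.5 ± 5.61 to 510 ± 36.6 CPM). ITGAM, an integrin subunit of myeloid cells, rose by 6.28 ± 0.68 and IL2RG, the common cytokine-receptor gamma chain, by 6.19 ± 0.48. The largest falls included the alcohol dehydrogenases ADH6 (-6.26 ± 0.74) and ADH1C (-5.71 ± 0.72), the phosphatase PTPRO (-5.70 ± 0.22), CD200 (-5.58 ± 0.33) and CLDN2, a pore-forming claudin (-5.26 ± 0.18, from 140 ± 25.9 to 3.68 ± 0.866 CPM).

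**Figure D2:**
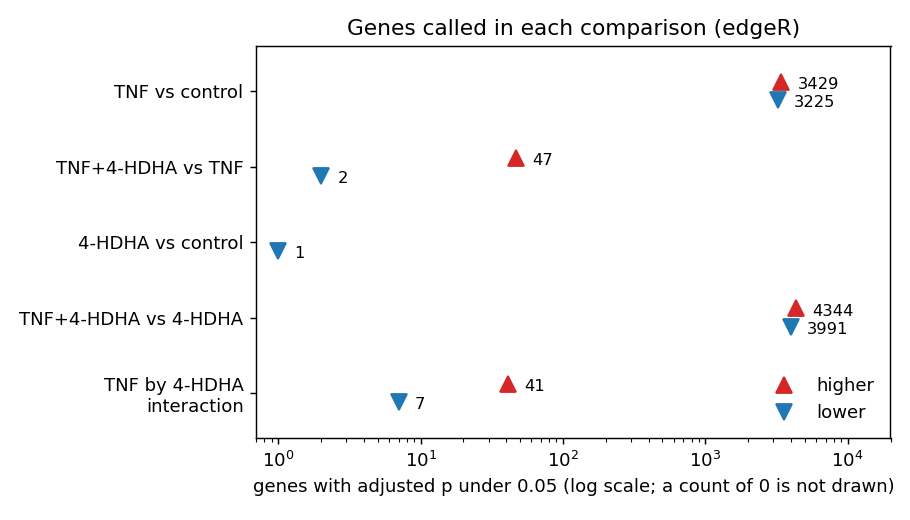
Number of genes called higher (upward triangles) and lower (downward triangles) in each of the 5 comparisons, on a log axis. TNF called 3429 genes higher and 3225 lower, while adding 4-HDHA to TNF called 47 higher and 2 lower.

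Inflammatory and interferon genes rose together under TNF. Of 34 NF-kB pathway genes 28 rose and 0 fell (29 and 0 adjusted over the list alone). Among them were NFKB2 (2.69 ± 0.06), the caspase inhibitor BIRC3 (4.99 ± 0.11), the feedback inhibitors TNFAIP3 (4.90 ± 0.17) and NFKBIA (2.81 ± 0.09) and the adhesion molecule ICAM1 (3.98 ± 0.11). Of 34 cytokines and chemokines 25 rose and 0 fell (26 and 0 adjusted over the list alone), including the neutrophil chemokines CXCL8 (4.93 ± 0.11, from 3.09 ± 0.109 to 94.3 ± 7.20 CPM) and CXCL1 (4.28 ± 0.17). Others were CXCL11 (2.86 ± 0.08), IL23A (5.10 ± 0.22) and IL32 (6.16 ± 0.35). All 49 interferon-stimulated genes tested rose (49 adjusted over the list alone), such as TRIM22 (3.85 ± 0.09), IFITM1 (2.70 ± 0.08), OAS2 (2.22 ± 0.08) and IFITM3 (1.64 ± 0.05). Of 32 antigen-presentation genes 21 rose and 1 fell (the same counts adjusted over the list alone). HLA-B changed by 3.36 ± 0.06 (131 ± 8.86 to 1340 ± 13 CPM), HLA-F by 3.03 ± 0.07, the peptide transporter TAP1 by 2.36 ± 0.06 and the protease CTSS by 2.90 ± 0.08. These 4 lists were called by camera (adjusted p = 1.7e-23, 7.3e-16, 1.6e-43 and 9.9e-14 in that order). They held with adjusted p = 0.0061, 0.0064, 0.023 and 0.011 with an estimated correlation. Of 25 mucosal antimicrobial and acute-phase genes 14 rose and 2 fell (14 and 3 adjusted over the list alone). Complement factor CFB was at 2.95 ± 0.10, the protease inhibitor PI3 at 3.29 ± 0.17 and lysozyme, LYZ, at -0.85 ± 0.05. Camera called that list (adjusted p = 0.00037), with adjusted p = 0.078 with an estimated correlation.

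Genes of cell death moved in several directions. Of 14 tested pro-apoptotic BCL2-family genes 9 rose and 0 fell (the same counts adjusted over the list alone). BMF was at 1.70 ± 0.08, BCL2L14 at 1.67 ± 0.19, BID at 0.63 ± 0.05 and PMAIP1 at 0.61 ± 0.08 (camera adjusted p = 0.00043, and adjusted p = 0.026 with an estimated correlation). Of 22 necroptosis and pyroptosis genes 14 rose and 2 fell (14 and 3 adjusted over the list alone). They included the nucleic-acid sensor ZBP1 (2.76 ± 0.14), inflammatory caspase CASP1 (2.53 ± 0.14), GSDMB (0.97 ± 0.06) and the necroptosis effector MLKL (0.86 ± 0.06), while RIPK3 was not called (0.17 ± 0.08, edgeR adjusted p = 0.13). Camera called this list (adjusted p = 7.3e-05), with adjusted p = 0.064 with an estimated correlation. Of 31 death-receptor and extrinsic caspase genes 11 rose and 6 fell (12 and 8 adjusted over the list alone; camera adjusted p = 0.12). TNFRSF1B, the second TNF receptor, was at 3.03 ± 0.13, TRAF3 at 1.04 ± 0.07 and CASP8 at 0.47 ± 0.08. Of 22 anti-apoptotic genes 4 rose and 8 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.34), and CFLAR, which blocks caspase 8, rose by 0.41 ± 0.05. Of 36 p53 target genes 8 rose and 11 fell (9 and 13 adjusted over the list alone; camera adjusted p = 0.43).

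Transcripts of the translation and respiration machinery fell. Of 76 cytosolic ribosomal protein genes 72 fell and 0 rose (73 and 0 adjusted over the list alone). Their median was -0.60, with RPLP0 at -0.94 ± 0.05 and RPSA at -1.02 ± 0.06 (camera adjusted p = 3e-36, and adjusted p = 0.14 with an estimated correlation). Of 76 nuclear-encoded respiratory-chain genes 44 fell and 2 rose (45 and 2 adjusted over the list alone). Among them were ATP5F1E (-0.54 ± 0.06) and COX7C (-0.58 ± 0.06; camera adjusted p = 1.5e-08, and adjusted p = 0.22 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 8 fell and 1 rose (8 and 2 adjusted over the list alone), MT-CO3 by -0.61 ± 0.08 (camera adjusted p = 0.035, and adjusted p = 0.59 with an estimated correlation). Of 54 mitosis and G2/M genes 30 rose and 1 fell (30 and 3 adjusted over the list alone). NUSAP1 was at 0.80 ± 0.07, BUB1 at 0.70 ± 0.08 and CCNB1 at 0.51 ± 0.05 (camera adjusted p = 1.8e-06, and adjusted p = 0.14 with an estimated correlation). Of 54 S-phase genes 9 rose and 19 fell (13 and 20 adjusted over the list alone; camera adjusted p = 0.17). That list held RRM2, a ribonucleotide reductase subunit, at -0.65 ± 0.05.

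Lists of epithelial identity, immediate-early and mesenchymal genes gave mixed results. Of 24 absorptive enterocyte genes 10 fell and 2 rose (the same counts adjusted over the list alone). They included the lectin LGALS4 (-1.77 ± 0.06), the glucose transporter SLC5A1 (-1.13 ± 0.06) and the peptidase DPP4 (-1.04 ± 0.07; camera adjusted p = 0.016, and adjusted p = 0.078 with an estimated correlation). Of 27 goblet-cell and mucin genes 13 fell and 6 rose (13 and 7 adjusted over the list alone; camera adjusted p = 0.12). AGR2 and CREB3L1 were at -1.35 ± 0.10 and -1.35 ± 0.04 and the gel-forming mucin MUC5AC at 2.47 ± 0.15. Of 42 immediate-early genes 14 fell and 8 rose (14 and 9 adjusted over the list alone). FOS was at -1.42 ± 0.09 and HBEGF at -1.55 ± 0.11 (camera adjusted p = 0.015, and adjusted p = 0.43 with an estimated correlation). Of 32 mesenchymal and matrix-remodelling genes 13 rose and 4 fell (the same counts adjusted over the list alone). Camera called this list (adjusted p = 0.015, and adjusted p = 0.21 with an estimated correlation), beside the uneven fibroblast marker levels given above. Of 32 junction genes 9 rose and 7 fell (11 and 8 adjusted over the list alone; camera adjusted p = 0.99), E-cadherin, CDH1, by -0.72 ± 0.06. Of 24 Wnt and stem-cell genes 8 rose and 6 fell (the same adjusted over the list alone; camera adjusted p = 0.74), with CD44 at -1.23 ± 0.06.

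Stress and lipid lists were called in part. Camera called 43 autophagy and lysosome genes higher (15 rose, 5 fell; adjusted p = 0.029, and adjusted p = 0.078 with an estimated correlation), with the autophagy receptor SQSTM1 at 1.41 ± 0.05. It called 27 heat-shock chaperones (10 rose, 0 fell; adjusted p = 0.0016, and adjusted p = 0.22 with an estimated correlation) and 40 NRF2 targets (16 rose, 6 fell; adjusted p = 0.012, and adjusted p = 0.21 with an estimated correlation) higher too. The same held for 32 cholesterol-synthesis genes (11 rose, 5 fell; adjusted p = 0.036, and adjusted p = 0.40 with an estimated correlation) and 13 LXR targets (5 rose, 0 fell; adjusted p = 0.010, and adjusted p = 0.22 with an estimated correlation). Adjusted over the list alone these 5 lists gave 15, 11, 17, 13 and 5 rises and 5, 0, 7, 5 and 0 falls. Of 39 polyunsaturated fatty-acid oxygenases and lipid-mediator receptors 9 rose and 7 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.69). Among them the prostaglandin E synthase PTGES rose by 3.21 ± 0.14, the epoxygenase CYP2J2 by 3.10 ± 0.25, and HPGD, which degrades prostaglandins, changed by -2.18 ± 0.17. The lists of endoplasmic reticulum stress (13 rose and 15 fell of 53, ATF5 by 1.56 ± 0.09 and HSPA5 by 0.66 ± 0.06), ferroptosis (3 and 8 of 33, the iron exporter SLC40A1 by -1.76 ± 0.07), PPAR targets (6 and 16 of 45, the lipid-droplet protein PLIN2 by 0.81 ± 0.11), fatty-acid synthesis (8 and 3 of 29), glycolysis (16 and 13 of 44), proteasome (11 and 5 of 31, PSMA5 by 0.54 ± 0.05) and replication-dependent histones (3 and 1 of 32) were not called by camera. Adjusted over the list alone they gave 15 and 17, 3 and 8, 6 and 17, 9 and 3, 16 and 13, 11 and 6, and 1 and 0. Markers of other cell types gave 0 rises and 0 falls of 14 for fibroblasts, 2 and 2 of 10 for leukocytes, 1 and 1 of 11 for endothelium and 2 and 2 of 8 for other cultured lines, the same counts adjusted over the list alone, and none of these lists was called. The median and camera's direction differed in sign for junction genes (0.03, lower), leukocyte markers (0.49, lower) and markers of other lines (-0.11, higher).

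The count of TNF calls stayed within 1.5 times of 6654 under every setting tried. The majority turned to lower genes, so no direction prevailed, in 3 settings and without any of 7 libraries. Higher and lower were 3221 and 3522 with at least 1 CPM in 3 libraries, 3503 and 3523 with DESeq2, and 3218 and 4117 with a GC and length offset chosen after seeing the data. They were 2806 and 2933 without control replicate 1, 2855 and 2997, 2650 and 2871, and 2649 and 2875 without TNF replicates 1, 2 and 3, and 3106 and 3328, 3085 and 3298, and 3100 and 3331 without TNF+4-HDHA replicates 1, 2 and 3. OR2I1P rose by 7.35 ± 0.87 but overlaps UBD, and PIK3R2 (-6.05 ± 1.85, edgeR adjusted p = 0.037) was read at 0.855 CPM in control replicate 3 against 45.3 and 44.8 in the other controls, so both values are uncertain. Without control replicate 3 UBD had 0 counts in the control, so its fold rests on that library, and C3 was at 7.82 and ITGAM at 7.38. TNFRSF6B was at 10.01 and LTB at 7.52 without control replicate 2, and ADH1C at -6.36 and ADH6 at -6.86 without TNF replicate 1.

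4-HDHA added to TNF was the central comparison, TNF+4-HDHA against TNF. It called 49 genes, 47 higher and 2 lower, with 1758 genes at an unadjusted p under 0.05. GOLGA4, a Golgi golgin (ENSG00000144674, chromosome 3, 37243191 to 37366879, plus strand), rose most, by 1.35 ± 0.12, from 31.9 ± 2.23 to 81.2 ± 4.32 CPM (edgeR adjusted p = 0.00078). The kinetochore motor CENPE rose by 1.31 ± 0.15 (10 ± 0.361 to 24.8 ± 2.18 CPM), the ciliary and centrosomal protein CEP290 by 1.28 ± 0.18 (7.92 ± 0.776 to 19.2 ± 0.966 CPM), CCDC18 by 1.20 ± 0.10 (edgeR adjusted p = 0.00031) and ANKRD12 by 1.13 ± 0.18.

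Further rises were in AKAP9, a scaffold at centrosome and Golgi (1.11 ± 0.13), the kinesin KIF20B (1.06 ± 0.12) and the spindle protein ASPM (1.04 ± 0.15). They also included the kinetochore protein CENPF (0.96 ± 0.10, from 69.5 ± 3.29 to 135 ± 4.92 CPM) and the golgin GOLGB1 (0.89 ± 0.09). The 2 genes that fell were the interferon-induced ISG15 (-0.29 ± 0.05, from 401 ± 11.6 to 327 ± 11 CPM, edgeR adjusted p = 0.036) and the histone gene H3-3B (-0.26 ± 0.05, edgeR adjusted p = 0.048). Of the 47 genes that rose, 41 had their 3 highest values of all 12 libraries in the TNF+4-HDHA group. Their median change was 0.74 under TNF, -0.19 for 4-HDHA without TNF and -0.17 for TNF against control. The last value uses the TNF libraries by which the 47 were picked, so the choice alone favours a negative value. Among the libraries of TNF+4-HDHA against TNF, summed hair-follicle markers were high in TNF replicate 1 (912 CPM) and TNF+4-HDHA replicate 3 (121 CPM).

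**Figure D3:**
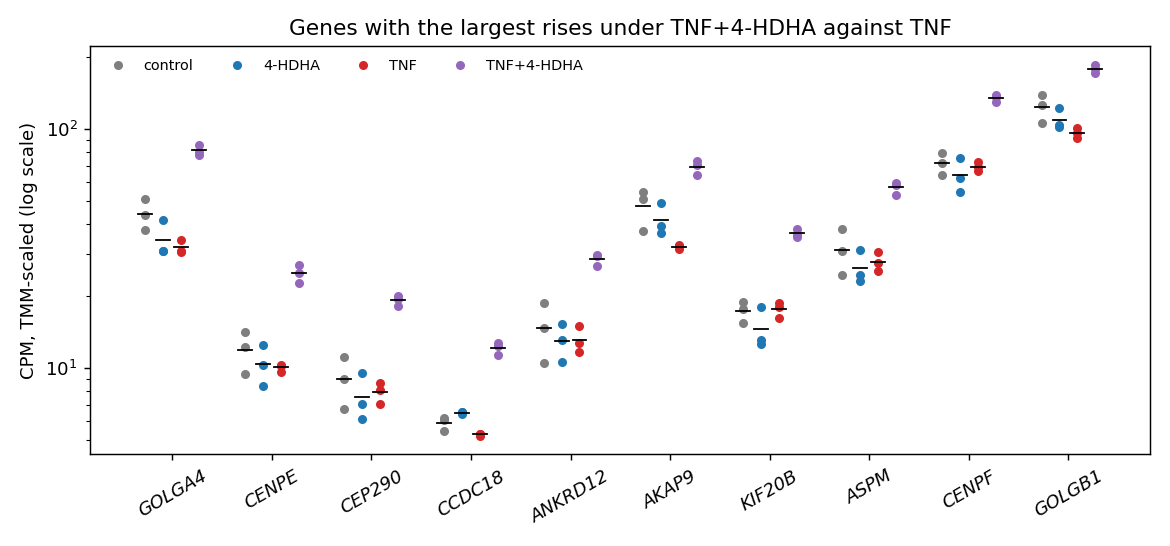
CPM per library, on a log axis, of the 10 genes with the largest called rises in TNF+4-HDHA against TNF; each point is 1 library and the bar is the group mean. GOLGA4 averaged 81.2 CPM with TNF+4-HDHA, against 31.9 with TNF, 34.4 with 4-HDHA and 44.1 in the control.

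None of the 16 TNF, cell-death and PPAR genes fixed in advance was called for 4-HDHA under TNF by edgeR, and 15 of them lay within 0.25 of 0. BIRC3 was at 0.21 ± 0.09 (edgeR adjusted p = 0.57), BCL2L1 at -0.15 ± 0.07 (edgeR adjusted p = 0.60) and the PPAR target ANGPTL4, a gene near the floor of detection, at 1.53. Among other genes named by rule, the apoptosis inducer BBC3 was at -0.47 ± 0.13 (edgeR adjusted p = 0.25) and GSDMD at -0.20 ± 0.06 (adjusted p = 0.22). The chaperone HSPH1 was at 0.36 ± 0.07 (adjusted p = 0.051) and IER2 at -0.29 ± 0.06 (adjusted p = 0.061).

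Of 54 mitosis and G2/M genes 4 rose and 0 fell (7 and 0 adjusted over the list alone), while the list's median was -0.01 and camera's direction was higher (adjusted p = 0.052). Of 49 interferon-stimulated genes 1 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 1.1e-08, and adjusted p = 0.30 with an estimated correlation). No member of the other lists was called over all genes. Camera called 18 of 38 lists, 16 lower and 2 higher, and 0 of the 18 held with an estimated correlation, where their adjusted p ran from 0.19 to 0.55. The higher lists were 54 S-phase genes (median 0.10, adjusted p = 0.40 with an estimated correlation) and 27 heat-shock chaperones (median 0.09, 3 members higher adjusted over the list alone, adjusted p = 0.25 with an estimated correlation). The lower lists included 42 immediate-early genes (median -0.14, 7 lower adjusted over the list alone), 53 endoplasmic reticulum stress genes (median -0.11, 11 lower and 1 higher adjusted over the list alone) and 14 pro-apoptotic BCL2-family genes (median -0.08, 0 called adjusted over the list alone), each with adjusted p = 0.19 with an estimated correlation. They also included 34 NF-kB genes (median -0.05, 0 called adjusted over the list alone, adjusted p = 0.30 with an estimated correlation) and 76 respiratory-chain genes (median -0.09, 0 called adjusted over the list alone, adjusted p = 0.30 with an estimated correlation). Fry, which compares a list with no other genes, called 1 of the 38 lists: the pro-apoptotic BCL2-family genes were lower (fry adjusted p = 0.023).

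The count of 49 varied with the test, the filter and the libraries fitted: 315 with DESeq2 (on 37111 genes, without the filter on low counts), 72 with limma-voom, 76 with a filter of at least 1 CPM in 3 libraries, 278 with only these 6 libraries fitted and 155 without control replicate 3, TNF replicate 1 and TNF+4-HDHA replicate 3 (chosen after seeing the data). Of the 49 calls 49, 49, 49, 49 and 39 were shared in that order. Fewer were shared on FPKM: 40 with log2(FPKM + 1), 36 with log2(FPKM + 0.1) and 20 with no filter. Without TNF replicates 1, 2 and 3 the shared calls were 12, 15 and 9. Without TNF+4-HDHA replicates 1, 2 and 3 they were 13, 12 and 13. The near absence of falls did not hold: higher and lower were 186 and 129 with DESeq2, 207 and 71 with only these 6 libraries, 91 and 64 without those 3 libraries and 204 and 123 without control replicate 3. The total was 327 without control replicate 3, 17, 17 and 10 without TNF replicates 1, 2 and 3, and 18, 19 and 13 without TNF+4-HDHA replicates 1, 2 and 3. Control replicate 3 is not in this comparison, but the spread was pooled over all groups. The median SD of log2 CPM was 0.162 in the control and 0.08 to 0.09 in the other groups.

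4-HDHA without TNF was the check on undisturbed cells. Only MEG3, a long noncoding RNA (ENSG00000214548), was called by edgeR, with 2305 genes at an unadjusted p under 0.05. MEG3 had 39, 59 and 87 counts in the control libraries and 0 in each 4-HDHA library, so it was at least 60.7-fold lower, taking a floor of 3 counts over the group (edgeR adjusted p = 0.0040). It was present in every TNF library (120, 95 and 105 counts) and TNF+4-HDHA library (97, 76 and 185 counts). MEG3 lies outside the rule for named genes and was chosen after its values were seen. Fibroblast markers moved with it, from 88.2 ± 61.6 CPM in the control to 19.4 ± 2.6 with 4-HDHA (SD, n = 3), as did COL1A1, at 9.23, 11.9 and 49.4 CPM in the controls and 4.39, 3.41 and 3.84 CPM with 4-HDHA.

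No other gene named by rule was called for 4-HDHA without TNF, with TRIM22 at -0.46 ± 0.08 (edgeR adjusted p = 0.20), the apoptosis effector BAX at 0.26 ± 0.06 (adjusted p = 0.20) and CXCL8 at -0.43 ± 0.11 (adjusted p = 0.27). Camera called 10 of 38 lists, 5 higher and 5 lower, and 0 held with an estimated correlation, where their adjusted p ran from 0.33 to 0.56. The higher lists were 76 ribosomal proteins (median 0.14, 4 higher adjusted over the list alone), 76 respiratory-chain genes (median 0.14), 54 S-phase genes (median 0.13), 31 proteasome subunits (median 0.10, 1 higher adjusted over the list alone) and 53 endoplasmic reticulum stress genes (median 0.04). Camera gave them, in that order, adjusted p = 0.45, 0.33, 0.45, 0.33 and 0.48 with an estimated correlation. The lower lists were fibroblast markers (11 of 14 lower adjusted over the list alone), endothelial markers (5 of 11), mesenchymal genes (8 of 32), mucosal antimicrobial genes (7 of 25) and interferon-stimulated genes (6 of 49). Camera gave these adjusted p = 0.45, 0.45, 0.33, 0.33 and 0.56 with an estimated correlation.

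Other settings called 394 genes (DESeq2), 0 (limma-voom), 0 to 7 (limma on FPKM), 4 (no filter), 2 (a filter of at least 1 CPM, or library size only), 16 (only these 6 libraries) and 179 without control replicate 3, TNF replicate 1 and TNF+4-HDHA replicate 3 (chosen after seeing the data). The count was 8 without control replicate 1, 14 without control replicate 3, 3 without 4-HDHA replicate 3, 6 without TNF replicate 1 and 5 without TNF+4-HDHA replicate 2, and MEG3 itself was not among the genes called with limma-voom or on FPKM.

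TNF+4-HDHA against 4-HDHA asked for the TNF response on the 4-HDHA background, with no library in common with TNF against control. It called 8335 genes, 4344 higher and 3991 lower, of which 1485 and 623 changed at least 2-fold. UBD, at 0 counts in the 4-HDHA libraries, was at least 4710-fold higher, taking a floor of 3 counts over the group. C3 rose by 9.39 ± 0.75 (0.753 ± 0.174 to 507 ± 11.7 CPM), LTB by 8.19 ± 0.55, TNFRSF6B by 8.18 ± 0.78, TNF itself by 7.40 ± 0.57 and SAA2 by 7.25 ± 0.60. ADH6 (-6.90 ± 0.77), PTPRO (-5.87 ± 0.22), CD200 (-5.48 ± 0.33) and CLDN2 (-5.02 ± 0.17) fell.

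**Figure D4:**
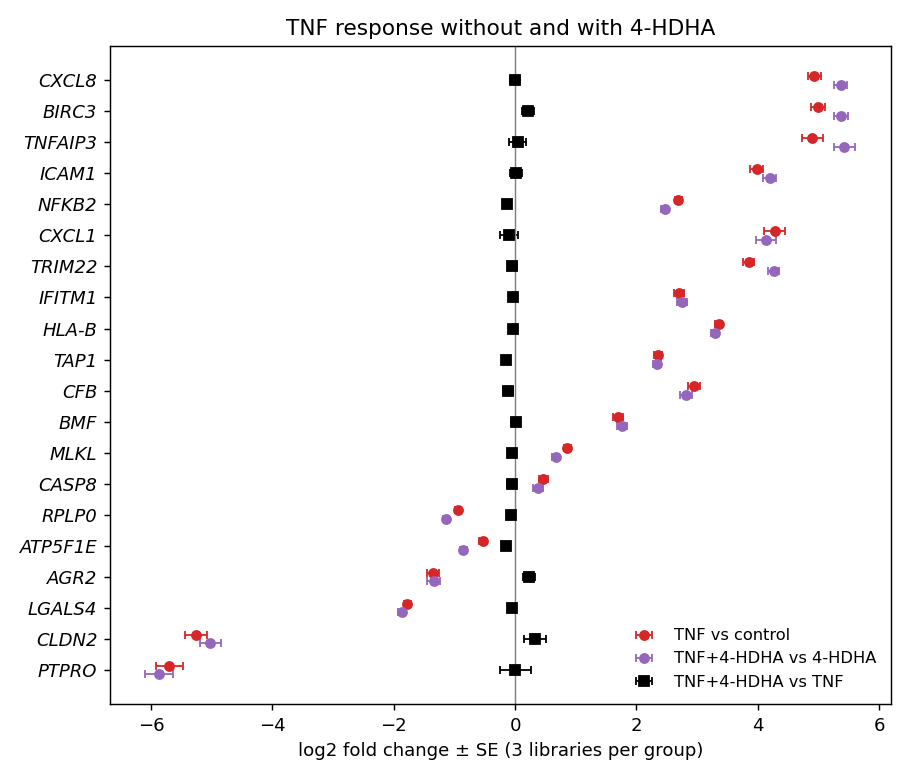
Log2 fold changes ± SE, with 3 libraries per group, of 20 genes for TNF against control, TNF+4-HDHA against 4-HDHA and TNF+4-HDHA against TNF. CXCL8 rose by 4.93 without and 5.36 with 4-HDHA, and the 4-HDHA effect under TNF lay near 0.

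Of 34 NF-kB genes 27 rose and 2 fell, NFKB2 by 2.47 ± 0.06 and BIRC3 by 5.37 ± 0.12, and of 34 cytokines and chemokines 26 rose and 1 fell, CXCL8 by 5.36 ± 0.11. Of 49 interferon-stimulated genes 47 rose and 0 fell, TRIM22 by 4.27 ± 0.09, and of 32 antigen-presentation genes 19 rose and 1 fell, HLA-B by 3.30 ± 0.06. Adjusted over the list alone these lists gave 27 and 2, 26 and 2, 47 and 0, and 22 and 1. Camera called all 4 with adjusted p = 0.012, 0.012, 0.044 and 0.012 with an estimated correlation. Of 76 ribosomal protein genes 75 fell and 0 rose (76 and 0 adjusted over the list alone), RPLP0 by -1.14 ± 0.05 (adjusted p = 0.12 with an estimated correlation). Of 76 respiratory-chain genes 61 fell and 3 rose (62 and 3 adjusted over the list alone), ATP5F1E by -0.85 ± 0.06 (adjusted p = 0.11 with an estimated correlation). Of 54 mitosis genes 36 rose and 9 fell (38 and 10 adjusted over the list alone), with KIF20B at 1.33 ± 0.12, CENPF at 1.07 ± 0.10 and HMMR at 1.05 ± 0.10 (adjusted p = 0.16 with an estimated correlation).

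Of 14 pro-apoptotic BCL2-family genes 9 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.056), BMF by 1.77 ± 0.08 and BAX by -0.42 ± 0.06, and CASP8 (0.38 ± 0.08) and CFLAR (0.56 ± 0.05) rose. Of 42 immediate-early genes 23 fell and 6 rose (24 and 7 adjusted over the list alone), JUN by -1.40 ± 0.10 and FOS by -1.60 ± 0.09 (camera adjusted p = 0.00034, and adjusted p = 0.28 with an estimated correlation). MUC5AC rose by 2.91 ± 0.15, LGALS4 changed by -1.86 ± 0.06, and ANGPTL4 rose by 3.35 ± 0.73 from 0.260 ± 0.0919 CPM. Of 14 fibroblast markers 10 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 0.068), among them ACTA2 (3.00 ± 0.49) and FBLN1 (3.70 ± 0.71, from 0.260 ± 0.0745 to 3.41 ± 1.42 CPM). These markers summed to 19.4 ± 2.6 CPM in the 4-HDHA libraries against 91.1 ± 48.8 with TNF+4-HDHA (SD, n = 3). Of 32 mesenchymal genes 21 rose and 5 fell (23 and 5 adjusted over the list alone; camera adjusted p = 0.0026, and adjusted p = 0.16 with an estimated correlation), beside those same marker levels. The count stayed within 1.5 times of 8335 under every setting tried. The majority of higher genes was lost with only these 6 libraries (4693 and 4693) and with a GC and length offset chosen after seeing the data (4128 higher and 4904 lower). It was also lost without control replicate 1 (4275 and 4325), TNF replicates 1, 2 and 3 (4109 and 4164, 3958 and 4092, and 3983 and 4111) and TNF+4-HDHA replicates 1, 2 and 3 (3537 and 3760, 3476 and 3679, and 3419 and 3677). With no scaling beyond library size the median of all genes shifted from 0.06 to 0.12, and 5177 genes were higher and 3288 lower. ADH6 was at -8.10 and ANGPTL4 at 2.36 without TNF+4-HDHA replicate 3, and LTB at 8.79, TNFRSF6B at 9.31 and SAA2 at 8.20 without 4-HDHA replicates 1, 2 and 3.

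Called in both TNF comparisons in the same direction were 2770 genes higher and 2672 lower, where independent lists of these sizes would share 706 and 610, and 15 genes were called in opposite directions. Across all 21104 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.442 and Spearman's rho = 0.617.

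The interaction, the 4-HDHA effect under TNF minus the effect without TNF, tests that difference itself. It called 48 genes, 41 higher and 7 lower, with 2486 at an unadjusted p under 0.05, and 35 of the 47 genes that 4-HDHA raised under TNF were among them. The interaction holds the same difference of TNF+4-HDHA and TNF libraries by which the 47 were picked. That overlap is thus favoured by the choice and is no separate evidence. GOLGA4 had the largest value (1.71 ± 0.17, edgeR adjusted p = 0.0051), followed by CEP290 (1.52 ± 0.25), CENPE (1.51 ± 0.22), KIF20B (1.31 ± 0.17), the zinc-finger gene ZNF117 (1.31 ± 0.23), and AKAP9 (1.31 ± 0.18). Next were ASPM (1.28 ± 0.21), UACA (1.13 ± 0.19), CENPF (1.12 ± 0.14) and ESF1 (1.11 ± 0.20). The 7 lower genes were SAC3D1 (-0.89 ± 0.16), CHIC2 (-0.81 ± 0.15), CCNQ (-0.61 ± 0.10), HSPBP1 (-0.46 ± 0.09), NAPRT (-0.43 ± 0.07), the histone variant H2AZ1 (-0.39 ± 0.06) and the citrate carrier SLC25A1 (-0.38 ± 0.07). None of the 16 genes fixed in advance was called by edgeR, with BIRC3 at 0.38 ± 0.14 (adjusted p = 0.30), and BAX was at -0.32 ± 0.08 (adjusted p = 0.12).

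Camera called 11 of 38 lists for the interaction, 3 higher and 8 lower, and 0 held with an estimated correlation, where their adjusted p ran from 0.11 to 0.52. The lower ones included 76 respiratory-chain genes (median -0.23, 12 lower adjusted over the list alone, adjusted p = 0.13 with an estimated correlation) and 76 ribosomal proteins (median -0.20, 14 lower adjusted over the list alone, adjusted p = 0.39 with an estimated correlation). They also included 31 proteasome subunits (median -0.20, 12 lower adjusted over the list alone, adjusted p = 0.11 with an estimated correlation) and 14 pro-apoptotic BCL2-family genes (median -0.16, 2 lower adjusted over the list alone, adjusted p = 0.11 with an estimated correlation). Fry called 7 lists and gave the pro-apoptotic genes its smallest value, for a lower interaction (fry adjusted p = 0.0051). Without TNF fry called the same list higher with 4-HDHA (fry adjusted p = 0.045). The higher ones included fibroblast markers (6 of 14 higher adjusted over the list alone, adjusted p = 0.52 with an estimated correlation). Of 54 mitosis genes 4 were higher and 0 lower (6 and 1 adjusted over the list alone), with a list median of -0.04 (camera adjusted p = 0.97).

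The interaction count was 634 with DESeq2, 54 with limma-voom, 82 with a filter of at least 1 CPM in 3 libraries, 27 with limma on unfiltered FPKM and 776 without control replicate 3, TNF replicate 1 and TNF+4-HDHA replicate 3 (chosen after seeing the data). With a GC and length offset, also chosen then, 48 were higher and 21 lower of 69. The excess of higher genes was smaller or gone in other settings, with 358 higher and 276 lower by DESeq2, 400 and 376 without those 3 libraries, and 356 and 366 without control replicate 3. The total was 722 without control replicate 3 and 9 without control replicate 2, 73, 10 and 11 without 4-HDHA replicates 1, 2 and 3, 30, 15 and 9 without TNF replicates 1, 2 and 3, and 12, 24 and 16 without TNF+4-HDHA replicates 1, 2 and 3.

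Over the 2042 TNF-responsive genes, 1429 higher and 613 lower by the mean TNF effect of both backgrounds, the interaction taken in the direction of the TNF effect had a median of 0.198 (95% bootstrap interval over genes, which are not independent, 0.176 to 0.225). The median TNF effect was 1.41 without and 1.82 with 4-HDHA, and 34.1% of these genes had a smaller effect with 4-HDHA. By fry the genes higher with TNF gave p = 0.037 for a higher interaction (n = 12 libraries) and the genes lower with TNF p = 0.12 for a lower one. Of the 2042 genes 250 had a group at 0, so the size of their fitted fold is uncertain, and they were kept in these medians. In 509 of the 2042 genes with a mean of at least 10 CPM the median was 0.067, and among those under 10 CPM it was 0.32. That difference lay in the genes higher with TNF (median interaction 0.023 and 0.437 at those levels), while the genes lower with TNF had -0.13 and -0.172. The fry p was above 0.05 without control replicate 3 (median 0.112), 4-HDHA replicate 2 (0.210) and TNF replicates 1, 2 and 3 (0.118, 0.191 and 0.181). Leaving out TNF replicate 1 or control replicate 3 moved the median by over 1.5 times. In a fit that left out control replicate 3, TNF replicate 1 and TNF+4-HDHA replicate 3, chosen after seeing the data, the median fell to 0.067 while the fry p was the smallest of all settings.

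Genes called with TNF and with the opposite sign when 4-HDHA was added to TNF numbered 14, and 1 gene was called with the same sign. Independent lists would give 8 of each, but these lists share the TNF libraries and are not independent. In 14505 genes with a mean of at least 1 CPM the 2 sets of fold changes had Pearson's r = -0.145 and a covariance of -0.0374, against a mean r of -0.485 and covariance of -0.0806 (range -0.1058 to -0.048) in 20 simulations of unchanged groups that shared the TNF libraries. The observed covariance was less negative than in every simulation. The simulations used 1 spread per gene for all groups, while the median SD of log2 CPM was 0.162 in the control and 0.08 with TNF. They may thus overstate the noise of the shared TNF libraries, and cannot tell whether sharing those was enough to give the covariance. With no gene changed they called 0 genes with opposite signs, so they set no level for the count of 14. The count was 88 with DESeq2 and 59 without control replicate 3, TNF replicate 1 and TNF+4-HDHA replicate 3 (chosen after seeing the data). It was 7 and 125 without control replicates 2 and 3, 22 and 6 without 4-HDHA replicates 1 and 2, 8, 6 and 4 without TNF replicates 1, 2 and 3, and 4, 8 and 3 without TNF+4-HDHA replicates 1, 2 and 3.

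The 4-HDHA effects with and without TNF, which share no library, correlated across 21104 genes with Pearson's r = 0.216 and Spearman's rho = -0.033, so the 2 measures differed in sign. Pearson's r was 0.047 with no filter, 0.068 with DESeq2 and 0.042 without control replicate 3, TNF replicate 1 and TNF+4-HDHA replicate 3 (chosen after seeing the data). Without TNF replicate 1 Pearson's r was -0.283, and the jackknife standard error over libraries was 0.505.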

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

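Of the tests in this part, those of hair-follicle RNA in TNF replicate 1 and TNF+4-HDHA replicate 3 and of a shift of the cell cycle, and the fits without the most hair-rich library of 3 groups and with a GC and length offset, were chosen after the result was seen.

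The 4-HDHA effect differed with and without TNF, by the interaction test, in 48 genes. The interaction log2 fold changes were 1.71 for GOLGA4, 1.52 for CEP290, 1.51 for CENPE, 1.31 for KIF20B, 1.31 for ZNF117, 1.31 for AKAP9, 1.28 for ASPM, 1.13 for UACA, 1.12 for CENPF and 1.11 for ESF1. On the lower side they were -0.89 for SAC3D1, -0.81 for CHIC2, -0.61 for CCNQ, -0.46 for HSPBP1, -0.43 for NAPRT, -0.39 for H2AZ1 and -0.38 for SLC25A1. Of these 17 genes 3 stayed called in every setting and 14 lost the call in some. In 60 drawn splits of the 12 libraries, the real one included, 1 gave as many called genes, a share under 0.05. The real split called 48 and the others at most 30. As the design text calls the replicates technical, this weighs the labels only against the spread between these libraries. It does not exclude a chance difference between the cultures. Leaving out control replicate 3 gave 722 genes and leaving out control replicate 2 gave 9, with 73, 10 and 11 without 4-HDHA replicates 1, 2 and 3, 30, 15 and 9 without TNF replicates 1, 2 and 3, and 12, 24 and 16 without TNF+4-HDHA replicates 1, 2 and 3.

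The 47 genes that rose with 4-HDHA under TNF have long transcripts (median 7917 bases against 2657 for tested genes) of low GC content (38.6% against 49.3%). The nearest genes in length, GC content and expression had a median of 0.09 (95% bootstrap 0.07 to 0.13) against 0.74. That gap alone cannot decide on a bias, as the 47 were picked for their rise and the nearest genes whatever their change. The nearest genes lay above the median of all tested genes (-0.0038), and 19 of the 718 distinct ones were among the 47. With the offset 44 of the 47 stayed called, at a median of 0.63. That argues against a smooth trend with length and GC content as the whole cause. Without TNF replicate 1 and TNF+4-HDHA replicate 3 the median of the 47 was 0.71 (0.59 to 0.75). This cannot test hair-follicle RNA as a cause. None of the 47 overlapped between the groups over all 6 libraries, so each would stay higher without any 2. A general shift towards mitosis is argued against, as the fixed mitosis list had a median of -0.01 (-0.04 to 0.03). For chance, 10 splits of 6 libraries cannot give a share under 0.05: the real split called 49 genes and the highest other called 2, so 1 of 10 was as large. An effect of 4-HDHA in TNF-treated cells may underlie these rises, as a hypothesis found and examined on the same data, and a difference in handling or RNA quality between the TNF and TNF+4-HDHA libraries stays open as untested. Some of these genes also varied together between libraries of 1 treatment. In control replicates 1, 2 and 3 GOLGA4 was at 51, 43.5 and 37.8 CPM, CEP290 at 11.1, 8.94 and 6.73 CPM and AKAP9 at 54.6, 50.8 and 37.3 CPM.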

How the results depend on the processing

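The fit without control replicate 3, TNF replicate 1 and TNF+4-HDHA replicate 3, each the richest of its group in hair-follicle transcripts, and the GC and length offset were chosen after seeing the data. The cause of the changes below was not tested. The spread was pooled over all groups and was largest in the control (median SD of log2 CPM 0.162, against 0.08 to 0.09 in the other groups). A low count of 4-HDHA calls therefore does not show that few genes changed. TNF calls (5518 to 8278 on leaving out 1 library) and TNF calls in the presence of 4-HDHA (6920 to 9627) stayed within 1.5 times of 6654 and 8335 throughout.

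Calls for 4-HDHA under TNF (49) moved to 76 with at least 1 CPM in 3 libraries, 315 with DESeq2, 278 with only the libraries compared and 155 without those 3 libraries, and ranged from 10 to 327 on leaving out 1 library. Calls for 4-HDHA without TNF (1) moved to 2 with library size only, 4 with no filter, 2 with at least 1 CPM, 394 with DESeq2, 0 with limma-voom, 16 with only the libraries compared, 0 with log2(FPKM + 0.1) and 7 with unfiltered FPKM. It also moved to 179 without those 3 libraries and 2 with the GC and length offset, and ranged from 1 to 14. Interaction calls (48) moved to 82 with at least 1 CPM, 634 with DESeq2, 27 with unfiltered FPKM and 776 without those 3 libraries, and ranged from 9 to 722. The overlap of opposite calls (14) moved to 88 with DESeq2 and 59 without those 3 libraries, and ranged from 3 to 125. The signed interaction (0.198) ranged from 0.112 to 0.222 and was 0.068, with fry p = 0.27 (n = 12 libraries), when no minimum fold was set, which adds genes of small TNF effect. The correlation of 4-HDHA effects (0.216) reversed to -0.283 without TNF replicate 1, the lowest value on leaving out 1 library, and reached 0.42. It was 0.047 with no filter and 0.068 with DESeq2.

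Lists called by camera fell with an estimated correlation from 19 to 5 for TNF, 18 to 0 for 4-HDHA under TNF, 10 to 0 for 4-HDHA without TNF, 15 to 4 for TNF in the presence of 4-HDHA and 11 to 0 for the interaction. On leaving out 1 library they ranged from 17 to 20, 15 to 20, 6 to 14, 15 to 18 and 9 to 17, with 6 without control replicate 1 and 17 without control replicate 3. Of the called genes the text names, 75 of 77 for TNF, 7 of 12 for 4-HDHA under TNF, 0 of 1 for 4-HDHA without TNF, 29 of 31 for TNF in the presence of 4-HDHA and 3 of 17 for the interaction stayed called in every setting, and 0 reversed.

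The replicate numbers did not pair the libraries: in 18 pairs of the same number the deviations correlated at -0.257 to 0.248, with 3 over 0.1. With the replicate block the calls were 6537 for TNF, 45 for 4-HDHA under TNF, 3 for 4-HDHA without TNF, 8180 for TNF in the presence of 4-HDHA and 46 for the interaction. Depth of 54 to 62 M counts limits genes near the floor, such as ANGPTL4 and MEG3.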

Other observations

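Of the tests in this part, the enrichment of annotation terms, the comparison of TNF replicate 1 with the other TNF libraries and the fit without the most hair-rich library of 3 groups were chosen after the result was seen. The bound for low-level RNA of other cells was set after the overall signed interaction was seen and before its values by level.

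Among the 44 annotated genes that rose with 4-HDHA under TNF, 9 carried the term centrosome in the deposited annotation, where 1.17 were expected (Fisher's exact test, adjusted p = 0.0045 over 2349 terms). The terms cell division (7 genes, 0.94 expected) and cell cycle (8 genes, 1.37 expected) each had adjusted p = 0.043. In 10000 random sets matched on length, GC content and expression the means were 2.02, 1.40 and 2.11 genes, above the expected 1.17, 0.94 and 1.37. These sets cannot serve as a separate test of the terms. The terms were picked from 2349 for their small Fisher p in the same genes, and the matched comparison was not adjusted for that choice. CENPE, CENPF, ASPM, KIF20B, CEP290 and AKAP9 are known proteins of the spindle, kinetochore or centrosome.

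Among the genes that rose with TNF against control, the lysosome term held 99 of 2943 annotated genes where 62.9 were expected (Fisher's exact test, adjusted p = 0.00037) and the P-body term, for cytoplasmic granules of mRNA decay, held 30 where 13.69 were expected (adjusted p = 0.0017). Among the 2788 genes that fell, the smallest p were for translation and ribosome terms. Cytoplasmic translation held 73 genes where 15.41 were expected (Fisher's exact test, adjusted p = 3.2e-40). Focal adhesion held 92 where 48.12 were expected (adjusted p = 1.1e-08) and the mitochondrial ATP synthase complex 17 where 3.57 were expected (adjusted p = 1.1e-08). A gene can carry several terms. Whether the focal adhesion count rests on ribosomal protein genes was not tested.

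Hair-follicle transcripts summed to 722 CPM in control replicate 3, 912 CPM in TNF replicate 1, 127 and 88.7 CPM in control replicates 2 and 1 and 121 CPM in TNF+4-HDHA replicate 3. A response of the cells to treatment is argued against, since TNF replicate 1 held 93.6 times the level of the highest other TNF library. RNA or reads from skin or hair follicle are a candidate source: over 22 hair markers not looked at before, control replicate 3 and TNF replicate 1 kept the same proportions (across markers, Pearson's r = 0.99, Spearman's rho = 0.98). The most abundant markers in TNF replicate 1 were TCHH at 241 CPM, KRT31 at 102 CPM, KRT85 at 94.1 CPM and KRT71 at 79.3 CPM, with the epidermal KRT5 at 76.4 CPM, and of 32 listed hair markers 1 was over 1 CPM in the 4-HDHA libraries. Where such RNA entered, in culture, extraction, library making or sequencing, was not tested, nor was the source of the fibroblast transcripts.

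The larger TNF effect with 4-HDHA had a median signed interaction of 0.198 over 2042 genes. Of these, 250 had a group at 0, so the size of their fitted fold is uncertain. In the 509 genes of at least 10 CPM the median was 0.067 (95% bootstrap 0.045 to 0.088). That lies under the bound of 0.5 of the overall median set for low-level RNA of other cells that is missing from the 4-HDHA libraries, which may account for part of it in the genes higher with TNF, whose median interaction was 0.437 under 10 CPM and 0.023 at or above. It does not account for the genes lower with TNF, as missing RNA would raise their interaction, which was -0.172 under 10 CPM and -0.13 at or above. Of 60 drawn splits 1, the real one, was as large, a share under 0.05, and the highest other reached 0.179. This does not exclude chance, as the design text calls the replicates technical. The 4-HDHA libraries also all held low levels of hair-follicle and fibroblast transcripts, so the libraries were not alike apart from their labels. A stronger TNF response in the presence of 4-HDHA stays open, and the median was 0.112 without control replicate 3 and 0.118 without TNF replicate 1.

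For the other comparisons 10 splits of 6 libraries cannot give a share under 0.05. TNF against control called 6654 genes in the real split and at most 1 in the others, so 1 split was as large, and TNF+4-HDHA against 4-HDHA called 8335 against at most 0, again 1 split. For 4-HDHA against control 4 splits called as many as the real 1, the highest other calling 1. Lists called by camera numbered 19 for TNF (1 split as large, highest other 14), 18 for 4-HDHA under TNF (1, highest other 14), 10 for 4-HDHA without TNF (3, highest other 12) and 15 for TNF in the presence of 4-HDHA (1, highest other 14). For the interaction 7 of 60 drawn splits called as many lists as the real 11, with 15 the highest other, so chance is not excluded there.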
